A study of Mus musculus with 18 samples.

How the data were processed

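Chromatin immunoprecipitation sequencing (ChIP-seq) was performed on frozen cerebral cortex of 3 wild-type adult female C57BL/6J mice aged 14 weeks, numbered 5, 7 and 9 in the labels. Each animal gave 5 ChIP libraries, against the histone marks H3K27ac and H3K4me1, RNA polymerase II with phosphorylated serine 5 (PolII_S5P), MBD3 and TDG, and 1 input sample. The 15 ChIP libraries have a peak list each, and the 3 input samples were not analysed here. Libraries with the same number come from the same animal per the labels, so the numbers pair the samples, and the replicates are separate animals.

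Per the submitters' processing notes, bcl2fastq 2.20, Trim Galore 0.6.7, SAMtools 1.16.1, Picard 2.18.29 and MACS2 2.2.7.1 were used, with the mouse build mm39 (hg38 is listed too). The aligner and the control used for peak calling are not given in the sources used here. The deposited lists are in the narrowPeak layout, with 1 list per library rather than per pooled group. Their contig names belong to mm39, and all coordinates below are on that build, counted from 1. The authors deposited for each peak an integer score, a fold enrichment (a ratio of the pileup to the local background), a −log10 p-value, a −log10 q-value and the summit offset, which is another kind of number giving the distance in bp from the peak start. The lowest −log10 q-value in a list lay between 1.30 and 1.44. The fold enrichment is the authors' value and was used only to rank, filter or describe peaks within a list. Read depth is unknown, so differences in the number of peaks between libraries cannot be separated from differences in depth or in antibody efficiency.

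Peaks on chromosomes 1 to 19, X and Y were analysed. The MBD3 and TDG lists write unplaced sequences with a repeated prefix where the other 3 antibodies do not, which marks a difference in processing between these lists. This difference cannot be told apart from the antibody, since each antibody falls wholly on 1 side. Peaks were called shared when they overlapped by at least 1 bp. The percent of TDG peaks overlapping a list of the same animal was compared with 1000 random placements of the TDG peaks on their own chromosomes, and that of MBD3 peaks with 200, both two-sided, with Benjamini-Hochberg adjustment over 12 and 9 tests. Random positions were drawn between the outermost peaks of a chromosome without removing assembly gaps or unmappable sequence, which lowers the random percentage and raises the fold over it. The number of peaks (log10) and the Jaccard index (shared bases over all covered bases) were compared between antibodies by permuting antibody labels over the 15 libraries 100000 times. Pairs of antibodies, 3 libraries against 3, were compared by a two-sided exact permutation test, whose smallest p is 0.1. Odds ratios over H3K27ac peaks were Mantel-Haenszel estimates over 20 strata (PolII_S5P peak or none, H3K4me1 peak or none, 5 classes of H3K27ac fold enrichment), and intervals of shares are exact binomial intervals at the 95% level. Peaks are not replicates, and these intervals cover counting error only. TDG regions are TDG peaks of the 3 animals merged where they overlap.

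The design written before the data were examined included the share of peaks at promoters, CpG content, 18 gene lists and named genes. These need an annotation or sequence on mm39. The only gene table used here is on GRCm38.p6, and coordinates were not moved between builds, so these results were not run, and the table served only for counts of genes per chromosome. Regions are given by position for the same reason. In their place, merged TDG regions, the odds ratio over H3K27ac peaks and MBD3 at H3K4me1 peaks with or without H3K27ac were analysed. Regions were named by a rule written after the numbers of peaks were seen and before any overlap was computed. It takes the 10 TDG regions with peaks in all 3 animals and the best mean rank of fold enrichment, the 5 best TDG regions that also have H3K27ac and PolII_S5P peaks in every animal, and the 3 best regions of each other antibody. The comparison of H3K27ac peaks with and without PolII_S5P, the matched random placement on H3K27ac peaks and the shares on chromosome X were added after seeing the data.

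The overlap code was tested on simulated lists, where planted shares were recovered with an error of 0 percentage points in 3 lists and 2 of 60 random lists passed the threshold of 0.05. For the odds ratio over 60000 simulated sites, whose rates differed only between the 20 strata used, a planted value of 4 gave 3.87 with strata and 5.71 without. Alternatives covered the q-value threshold (−log10 q of at least 5), the overlap rule, lists of equal length, merging of peaks within 500 bp, other sequences, leaving out each animal and the pairing by animal. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.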

Results

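Peak lists from the cerebral cortex of 3 mice were compared for 5 antibodies. H3K27ac marks active promoters and enhancers, and H3K4me1 is found mainly at enhancers. PolII_S5P is the form of RNA polymerase II found near transcription start sites. MBD3 is a subunit of the NuRD chromatin remodelling and deacetylase complex. TDG (thymine DNA glycosylase) excises thymine from G:T mismatches and oxidized forms of methylcytosine. The title of the series names active promoters and an interaction of TDG with MBD3/NuRD, and the comparisons below ask where the peaks of these proteins lie relative to each other.

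H3K27ac gave the most peaks and TDG by far the fewest. H3K27ac libraries had 64852 ± 5429 peaks (SD, n = 3), covering 64.6 ± 10.0 Mb, and MBD3 libraries had 53037 ± 12090 peaks, covering 30.3 ± 10.2 Mb. H3K4me1 followed with 34052 ± 11552 peaks and PolII_S5P with 12305 ± 7711. TDG libraries had 130, 256 and 957 peaks in animals 5, 7 and 9, covering 0.148 ± 0.145 Mb (SD, n = 3). TDG peaks were also the narrowest, with a median width of 284 bp averaged over animals, against 622 bp for H3K27ac.

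Antibody accounted for most of the variance of the log10 number of peaks (eta squared 0.941, permutation p = 1e-05 over 15 libraries, the smallest that 100000 permutations can give). In 8 of 10 pairs of antibodies the libraries of 1 antibody all lay above those of the other, with an exact permutation p of 0.1, the smallest that 3 against 3 allows (adjusted p = 0.125). The other 2 pairs, MBD3 with H3K27ac and MBD3 with H3K4me1, had an exact p of 0.2. Within an antibody, PolII_S5P ranged from 4409 to 19816 peaks and TDG from 130 to 957.

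**Figure D1:**
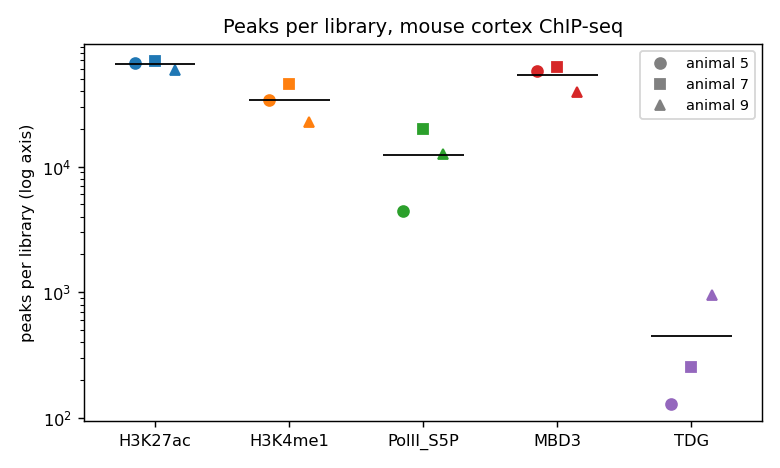
Number of peaks per library on a log axis, by antibody; each symbol is 1 animal and the line is the mean of 3. TDG lists hold 130 to 957 peaks and H3K27ac lists 58679 to 68887.

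Peak lists of the same antibody resembled each other in different animals. The mean Jaccard index was 0.574 between H3K27ac lists, 0.469 between MBD3 lists, 0.25 between PolII_S5P lists, 0.239 between H3K4me1 lists and 0.115 between TDG lists. Across antibodies it was 0.0560, the nearest pair being H3K27ac with MBD3 at 0.229. The index is capped by the ratio of covered bases. Lists of unlike length, such as TDG (0.148 Mb) and H3K27ac (64.6 Mb), therefore score low whatever their overlap, which also enters the difference below. Each of the 15 libraries was most similar to a library of its own antibody. The difference between same and different antibodies, 0.273, had a permutation p of 1e-05 (one-sided, the smallest attainable). Different antibodies in the same animal had an index of 0.0585, against 0.0547 in different animals.

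Some regions stood out in every animal. The strongest PolII_S5P peaks lay at chromosome 11, 87313378 to 87314052, with fold enrichments of 78.3, 150 and 141 in animals 5, 7 and 9, and carried H3K27ac and MBD3 peaks in all 3 animals. Another lay nearby at 87317325 to 87317853 (47.5, 89.9 and 68.9), and the last at chromosome 12, 54743403 to 54743962. For H3K27ac the strongest regions were at chromosome 9, 41489054 to 41495776 (fold 23.3, 23.0 and 21.3), chromosome 10, 14082240 to 14094730, and chromosome 2, 7398147 to 7401556, and all 3 carried MBD3 in every animal. For MBD3 they were at chromosome 3, 79343379 to 79343993 (59.9, 47.7 and 41.4), chromosome 6, 108298063 to 108299056, and chromosome 15, 10840389 to 10841233. The 3 strongest H3K4me1 regions all lay on chromosome 8 between 20024462 and 20708340, and each also had H3K27ac and PolII_S5P peaks in all 3 animals. None of these regions for H3K27ac, PolII_S5P or MBD3 carried a TDG peak, while all 3 of the H3K4me1 regions did, in 1, 1 and 2 animals in order of position.

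TDG peaks lay on the peaks of all 4 other antibodies more often than random placement gives. In animals 5, 7 and 9, 72.3%, 35.2% and 59.7% of TDG peaks overlapped an MBD3 peak of the same animal (mean 55.7 ± 18.9%, SD, n = 3), which is 33.3, 15.6 and 46.7 times the random percentage. For H3K27ac the shares were 61.5%, 26.6% and 61.7% (mean 49.9 ± 20.2%), or 17.3, 7.1 and 20.9 times random. PolII_S5P peaks held 24.6%, 14.1% and 20.1% of TDG peaks, or 182, 20.4 and 48.4 times random, and H3K4me1 peaks held 17.7%, 5.47% and 28.5%, or 14.3, 2.98 and 33.0 times random. All 12 overlaps passed the test (random-placement permutation, two-sided adjusted p = 0.002 each, the smallest attainable).

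The shares depend on the length of the lists. With all 4 other lists of an animal shortened to the same number of strongest peaks, a setting chosen after seeing the data, the means were 26.1% for MBD3, 27.6% for H3K27ac, 19.6% for PolII_S5P and 12.4% for H3K4me1, so MBD3 no longer held the largest share. In animal 5 MBD3 then held 22.3% of TDG peaks and both H3K27ac and PolII_S5P 24.6%. In animal 9 MBD3 held 32.3% and H3K27ac 36.6%, while in animal 7 MBD3 still held the largest share, 23.8% against 21.5% for H3K27ac. With the lists of each antibody cut to equal length over animals instead, and TDG to its 130 strongest peaks, MBD3 held 67.4%. H3K27ac held 54.6%, PolII_S5P 10.3 ± 12.4% and H3K4me1 6.15 ± 9.36% (SD, n = 3). The PolII_S5P and H3K4me1 shares thus differed widely between animals, although PolII_S5P kept its call in each (highest adjusted permutation p = 0.0024). Lists then still differed in length between antibodies, with 39326 peaks for MBD3, 58679 for H3K27ac, 4409 for PolII_S5P and 22611 for H3K4me1. This setting therefore does not remove the effect of length on the ranking of antibodies.

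The H3K4me1 overlap lost its call in some animals under some ways of shortening the lists. With all 4 other lists of an animal cut to the same number, it kept its call in animals 5, 7 and 9. The folds over random were 55.2, 2.95 and 42.9 (adjusted permutation p = 0.00218, 0.018 and 0.00218). At a −log10 q of at least 5 the folds over random were 25.1, 1.90 and 46.0 in animals 5, 7 and 9, and only animal 7 missed the threshold (2 of 127 TDG peaks, adjusted permutation p = 0.589), with a mean share of 9.07%. With lists of equal length per antibody the mean share was 6.15%, and the fold stayed at 17.3 in animal 5. It was 1.37 in animal 7 (2 of 130 peaks, adjusted permutation p = 0.863), and none of the 130 strongest TDG peaks of animal 9 overlapped H3K4me1 (adjusted permutation p = 0.615). In animal 7, 148 of 256 TDG peaks (57.8%) overlapped no peak of the other 4 antibodies, against 8.46% in animal 5 and 20.8% in animal 9.

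**Figure D2:**
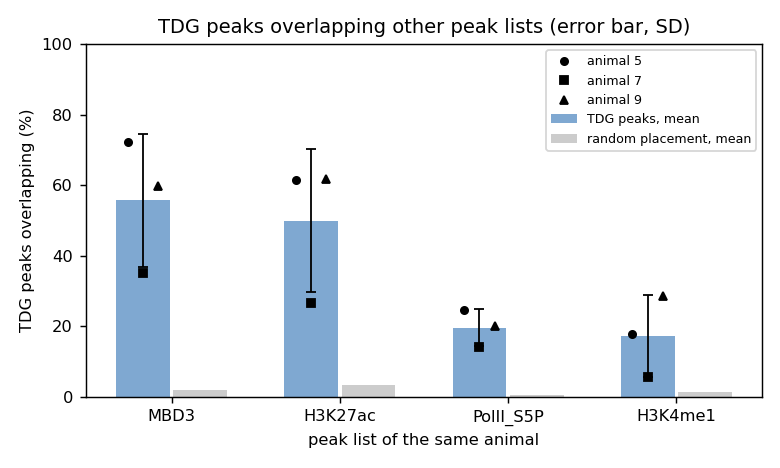
Percent of TDG peaks that overlap a peak of each other antibody in the same animal, with random placement beside it; bars are means of 3 animals, error bars SD and symbols single animals. MBD3 peaks held 35.2% to 72.3% of TDG peaks.

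Among TDG peaks on H3K27ac, MBD3 and PolII_S5P were still more frequent than at random places on H3K27ac peaks. MBD3 peaks lay at 80%, 91.2% and 76.6% of them in animals 5, 7 and 9, against 43.1%, 45.2% and 30.3% at random places, and PolII_S5P at 26.3%, 35.3% and 25.6%, against 3.09%, 12.7% and 8.94% (adjusted permutation p = 0.00257 in every animal). H3K4me1 went in different directions, with 21.3% against 21.4% in animal 5 (adjusted permutation p = 1), 13.2% against 29.6% in animal 7 (0.00674) and 38.6% against 17.2% in animal 9 (0.00257). Over H3K27ac peaks, the odds of a TDG peak were higher where an MBD3 peak was present, with stratified odds ratios of 2.54 (95% interval 1.47 to 4.39), 14.8 (5.32 to 41.4) and 5.61 (4.43 to 7.1) in the 3 animals. The mean log2 odds ratio was 2.57 ± 1.28 (SD, n = 3). These strata leave out site width, and with 10 classes of width added, after seeing the data, the odds ratios were 4.37 (1.98 to 9.62), 20.2 (5.67 to 71.9) and 5.02 (3.91 to 6.45).

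TDG regions shared by all animals formed a small set that carried MBD3 and H3K27ac more often, and H3K4me1 less often, than regions with TDG in 1 animal. Merging gave 55 regions with TDG peaks in all 3 animals, 72 in 2 and 1032 in 1, and random placement gave 0 regions in all 3. Of the 55, 52 (94.5%) had MBD3 peaks in at least 2 animals and 44 (80%) H3K27ac, against 51.7% and 52.4% of the regions with TDG in 1 animal (Fisher's exact adjusted p = 8.27e-11 and 5.85e-05). None had H3K4me1 in at least 2 animals, against 28.4% of regions with TDG in 1 animal (4.76e-08), and 9 (16.4%) had PolII_S5P, against 13.2% (0.539). The 72 regions with TDG in 2 animals did not lie between the others for every mark, with 70.8% for MBD3, 48.6% for H3K27ac, 15.3% for H3K4me1 and 23.6% for PolII_S5P. PolII_S5P was not called in any animal at 37 of the 55, and 25 combined MBD3 and H3K27ac in every animal with no PolII_S5P peak, 13 of them in the run on chromosome 6 described below (11 of 41 with regions within 100 kb counted once). With animal 5, 7 or 9 left out, 81, 94 and 62 regions were shared by the 2 remaining animals, a looser requirement that raises the count by construction. Peaks found in both other animals made up 42.3%, 21.5% and 5.75% of TDG peaks in animals 5, 7 and 9. TDG peaks in the 55 regions were also stronger, with median folds of 7.46, 9.55 and 9.86 in animals 5, 7 and 9, against 6.13, 4.19 and 4.41 for the other TDG peaks.

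These tests treat regions as independent, and most regions with TDG in 1 animal come from animal 9. With regions within 100 kb counted once, chosen after seeing the data, 41 shared regions were left, and the differences for MBD3, H3K27ac and H3K4me1 were 40.5, 20.0 and -27.3 percentage points (Fisher's exact adjusted p = 2.35e-07, 0.0203 and 8.85e-06). For PolII_S5P the difference rose to 10.2 points from 3.19, still short of the threshold (22.0% against 11.8%, Fisher's exact adjusted p = 0.0817). Among single animals, H3K4me1 lay at 11.7% of TDG peaks shared with any other animal against 40.7% of the rest in animal 5, and at 10% against 31.2% in animal 9. In animal 7 the shares were 6.82% and 4.76%, in the other direction.

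The strongest TDG region was at chromosome 13, 21894295 to 21895563, with fold enrichments of 19.3, 22.7 and 39.6 in animals 5, 7 and 9. It was followed by chromosome 3, 96407640 to 96408998 (15.5, 16.7 and 24.6), and both carried H3K27ac and MBD3 in all animals and no PolII_S5P peak. A region at chromosome 2, 18591802 to 18592055, had the same makeup. Chromosome 5, 129577853 to 129578419 (14.6, 15.9 and 20.9), and chromosome 7, 19295987 to 19296536 (13.1, 13.4 and 15.4), had H3K27ac, MBD3 and PolII_S5P in every animal. So did chromosome 9, 99450539 to 99451053. Chromosome 6, 113283786 to 113284283 and 126916513 to 126917037, had H3K27ac in every animal, PolII_S5P in 1 and 2 animals and MBD3 in 3 and 2. Another 3 of the 10 had no H3K27ac peak in any animal, at chromosome 2, 118877176 to 118877495, chromosome 3, 90383084 to 90383409, and chromosome 13, 23622793 to 23623050, with MBD3 in 2, 2 and 1 animals. The 2 remaining regions of the rule, at chromosome 8, 20705945 to 20706219, and chromosome 1, 78550381 to 78550770, had TDG in animals 5 and 9 and all of H3K27ac, H3K4me1 and PolII_S5P in every animal, but MBD3 in only 1 animal at each.

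A run of 13 of the 55 regions lay on chromosome 6 between 47631777 and 47740546, chosen for description after its position was seen. Of the 12 gaps between neighbouring midpoints, the 10 under 10 kb had a median of 4328 bp (range 4150 to 4468, SD 94.3), and the other 2 measured 10.4 and 54.6 kb. All 13 carried H3K27ac and MBD3 peaks in every animal, and no PolII_S5P or H3K4me1 peak was called there. The H3K27ac peaks were weak, with folds of 2.09 to 3.27, 1.82 to 3.43 and 1.22 to 2.31 in animals 5, 7 and 9. The medians of those lists were 3.70, 3.73 and 3.66. In animal 9 each of these H3K27ac peaks began inside its TDG region and ended beyond it. With this run removed after it was seen, 4 of the other 42 regions had another within 100 kb, against a mean of 0.316 in random draws of 42 MBD3 peaks, of which 8 in 1000 reached 4.

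**Figure D3:**
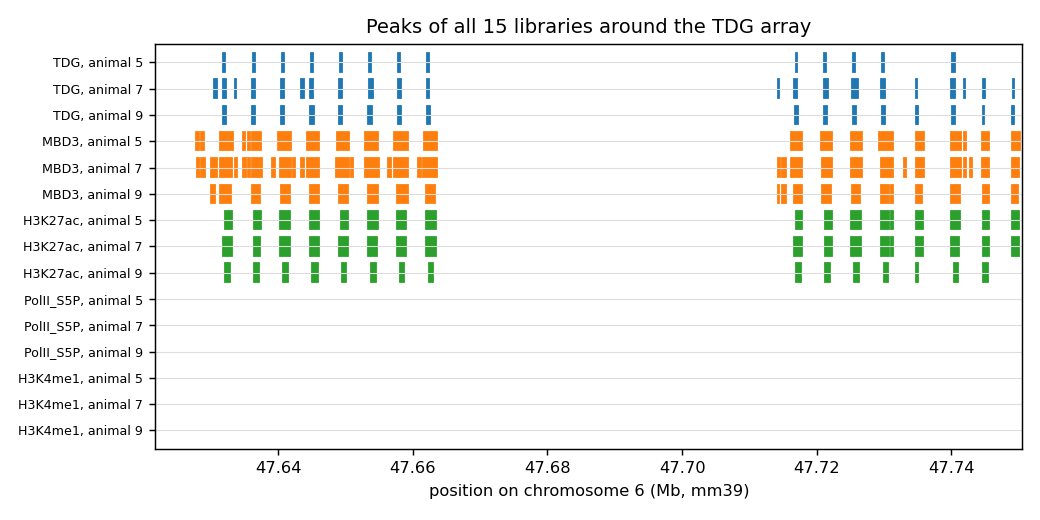
Peaks of all 15 libraries along chromosome 6 on mm39, 47621777 to 47750546; each line is 1 library and each box a peak to scale. TDG regions found in all 3 animals repeat at a median spacing of 4328 bp over the gaps under 10 kb, and the PolII_S5P and H3K4me1 lines are empty.

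MBD3 peaks overlapped H3K27ac more often than H3K4me1 or PolII_S5P. Of MBD3 peaks, 60.4 ± 1.23% overlapped H3K27ac (SD, n = 3), 15.2 times random, while 17.0 ± 5.62% overlapped H3K4me1 (10.5 times) and 11.6 ± 6.62% PolII_S5P (23.0 times). A further 35.8 ± 1.18% overlapped none of the 3, with a median fold enrichment at the percentile 40.9 of its list. The H3K27ac share fell to 46.9% with the summit inside the other peak and 49.9% with at least 0.5 of the peak's length covered. The H3K4me1 share was 6.48% at a −log10 q of at least 5, 9.88% with the summit inside the other peak and 10.4% with at least 0.5 of the peak's length covered. The PolII_S5P share was 5.66% under that coverage rule and 7.53% with lists of equal length. All 9 overlaps passed the test (random-placement permutation, two-sided adjusted p = 0.00995 each, the smallest attainable).

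The share of sites with MBD3 depended on which marks they carried. MBD3 was at 81.3 ± 8.31% of H3K27ac sites with PolII_S5P (SD, n = 3), 49.7 ± 7.45% of those with H3K4me1 and no PolII_S5P, and 36.8 ± 6.19% of those with neither. It was at 9.63 ± 3.01% of sites with H3K4me1 only and 9.25 ± 1.75% of PolII_S5P sites without H3K27ac, where random placement gave 2.38% and 2.40%. H3K27ac sites with PolII_S5P exceeded those without by 41.0 ± 1.81 percentage points (n = 3), and H3K4me1 sites without PolII_S5P that had H3K27ac exceeded those that did not by 29.7 ± 5.47 points, in the same direction in all 3 animals. The latter difference was 15.0 points with the summit inside the other peak and 15.7 with at least 0.5 of the peak's length covered. Sites with PolII_S5P are wider (median 1229 bp against 515 bp for H3K27ac alone). Within 5 classes of site width of equal number the difference kept its direction in 15 of 15 animal and width combinations, from 11.4 to 38.2 points. The same held for the H3K4me1 comparison in 15 of 15, from 15.2 to 44.8 points, a check added after seeing the data.

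**Figure D4:**
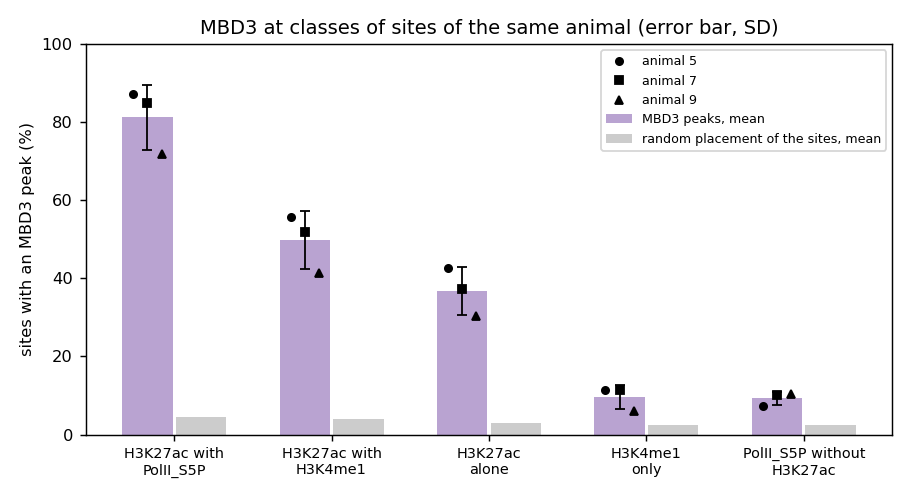
Percent of sites with an MBD3 peak, by class of site of the same animal, with random placement of the sites beside it; bars are means of 3 animals, error bars SD and symbols single animals. The share falls from 81.3% at H3K27ac sites with PolII_S5P to 9.63% at sites with H3K4me1 only.

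H3K4me1 was scarce on chromosome X. Chromosome X held 0.251% of H3K4me1 peaks on average (highest of 3 libraries 0.287%), against 1.41 ± 0.0376% for H3K27ac, 1.33 ± 0.165% for PolII_S5P and 1.44 ± 0.161% for MBD3 (SD, n = 3 each). The 3 H3K4me1 libraries lay below all 9 libraries of those antibodies, whose lowest share was 1.22% (two-sided exact permutation p = 0.00909 over 220 arrangements, the smallest attainable). This test ignores the pairing by animal and treats the 9 libraries of 3 antibodies as independent. It also does not account for H3K4me1 being singled out after the shares were seen. Chromosome X spans 6.16% of the length covered by the analysed chromosomes. TDG lists had only 2, 13 and 14 peaks on X in animals 5, 7 and 9, so their shares are imprecise. They were 1.54%, 5.08% and 1.46%, with exact 95% intervals of 0.187 to 5.45%, 2.73 to 8.53% and 0.802 to 2.44%. Of these intervals, those of animals 7 and 9 lay above the highest H3K4me1 share.

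**Figure D5:**
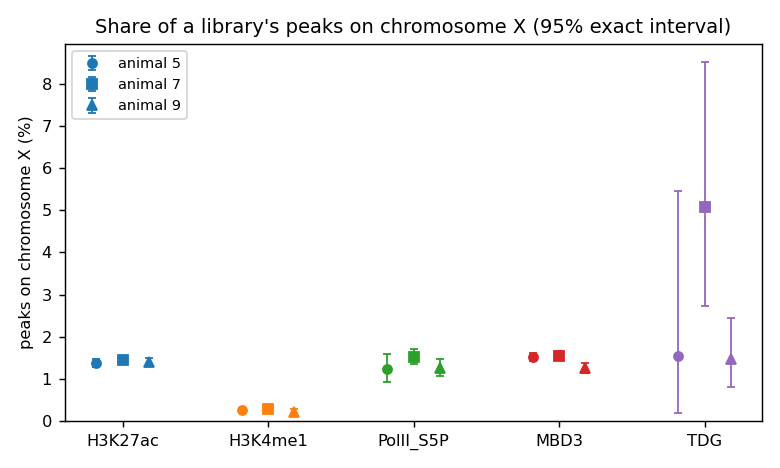
Percent of each library's peaks on chromosome X, by antibody; symbols are animals and bars exact 95% binomial intervals. H3K4me1 lists lie between 0.217% and 0.287% and the H3K27ac, PolII_S5P and MBD3 lists between 1.22% and 1.55%.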

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

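The tests of the control library on chromosome X and the comparison of the X share were chosen after the X shares were seen; the test of weak enrichment was written before. Chromosome X had a lower share of H3K4me1 peaks than of the other antibodies' peaks, with a difference of -1.14 percentage points from the mean of H3K27ac, PolII_S5P and MBD3. Weak enrichment near the calling threshold may contribute, since the X share of H3K27ac was 0.791% in the weakest against 1.90% in the strongest class of 5 in animal 5 and 0.827% against 1.84% in animal 7 (1.36% against 1.17% in animal 9), but as the whole cause it would bring the weakest class down to the H3K4me1 share, at most 0.287%. A control library with too much or too little X, if shared by both marks of an animal, would act on both. The H3K4me1 share was at most 0.198 times the H3K27ac share. This cannot decide, since the control of each library is not given. Such a control could also act unequally on marks of unlike median fold enrichment (3.01 for H3K4me1 and 3.70 for H3K27ac). A property of H3K4me1 on the female X, where 1 of the chromosomes is inactive, may contribute, and no biological explanation was tested because all mice were female.

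Peaks outside chromosomes 1 to 19, X and Y were not used in the comparisons, and the libraries named here had more than the 3 peaks taken as the limit that a count of 0 allows. The TDG list of animal 5 had 12 mitochondrial peaks, with fold enrichments of 2.95 to 5.59. The TDG lists of animals 9 and 7, with 1 and 0, were not above the limit. On unplaced sequences, H3K27ac had 5 and 4 peaks in animals 5 and 9, and H3K4me1 had 5 and 10 in animals 7 and 9. PolII_S5P had 9, 11 and 14 in animals 5, 7 and 9, and MBD3 had 8, 8 and 5. TDG had 7 and 8 in animals 7 and 9.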

How the results depend on the processing

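Random places on H3K27ac, equal lists for all antibodies, removal of sites lacking only H3K27ac, the odds ratio with no strata or with width added and regions within 100 kb counted once were chosen after seeing the data; the rest were planned. Leaving out an animal cannot change tests made within each animal, so those 30 values were not counted. Of 79 alternative values with a p, over 13 results and 15 settings, 76 kept their direction and side of the threshold, judged on the mean over animals and the highest p. For 3 results without a p (the odds ratio and both differences in MBD3 share), all 20 alternatives over 8 settings kept their direction, with 95% intervals on 1 side of no effect in every animal. The exceptions were all the overlap of TDG with H3K4me1: 9.07% at a −log10 q of at least 5 (fold in animal 7 1.90, from 2.98), 6.15% with equal numbers of peaks per antibody (1.37 in animal 7, and 0 from 33.0 in animal 9), and 24.4% of TDG peaks on H3K27ac against random places on H3K27ac (folds 0.993, 0.447 and 2.25 in animals 5, 7 and 9, reversed past the threshold in animal 7), and the cause was not tested. The number of TDG regions was 127 when 2 of 3 animals sufficed and 62 to 94 when 1 animal was left out, the highest without animal 7. Both rise by construction, since peaks in 2 animals then suffice. The X ratio of H3K4me1 to H3K27ac was 0.0927 at the stricter q and 0.117 with equal numbers. With the replicate block, labels permuted within animals, eta squared stayed 0.941 (exact permutation p = 6.94e-05, the smallest attainable) and the Jaccard difference 0.273 (permutation p = 8e-05), and the block changed no call. Comparing animals with each other left every overlap past its threshold. Promoter windows, transcript start choices, promoter placement, CpG bins, gene list backgrounds and repeat masking were not run, since they need mm39 annotation or sequence. Lists of equal length were not applied to the number of peaks, which they fix.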

Other observations

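The test of transfer RNA genes and that of H3K27ac sites were written before their values were seen; those of active chromatin, pile-ups, carry-over, shared controls and the width of H3K27ac sites were chosen after. H3K27ac sites on chromosome X had H3K4me1 peaks less often than matched autosomal sites in all 3 animals, a comparison added after seeing the data and with no test. Of H3K27ac peaks on X, 4.46 ± 1.19% had an H3K4me1 peak (SD, n = 3), against 26.7 ± 7.85% of autosomal peaks of the same fold and width. For MBD3 the shares were 49.9 ± 14.8% and 45.1 ± 8.20%, and for PolII_S5P 12 ± 8.01% and 11.3 ± 6.65%. On chromosome Y, 132 peaks were called over the 15 libraries of these female mice, and 131 of them lay in the Mb starting at 90 Mb.

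The TDG regions found in all 3 animals may be transfer RNA gene clusters, since a run of them lies on chromosome 6 without PolII_S5P. Over 20 chromosomes their number had a Spearman's rho of 0.438 with that of tRNA genes in the GRCm38.p6 table (permutation p = 0.0545, adjusted 0.0982 over 9 relations; Pearson's r 0.432, p = 0.0541, adjusted 0.0752), 0.380 with protein-coding genes and 0.602 with MBD3 peaks (adjusted 0.0178), and without chromosomes 13 and 6, the farthest from the median, rho with tRNA genes was 0.289 and r 0.508. Regions with TDG in 1 animal had an r of 0.427 and a rho of 0.345 with tRNA genes, so the relation is not particular to the shared regions; the planned bound on p was missed, but the interval of rho, -0.0200 to 0.744, covers both readings, and with regions within 100 kb counted once r was 0.442 for tRNA and 0.493 for protein-coding genes and rho 0.411 and 0.393, so the 2 cannot be told apart with 20 chromosomes. Pile-ups at repeats might show in all antibodies, and 1.82% of the regions had an H3K4me1 peak in any animal. This cannot decide, since the near absence of H3K4me1 was known when the test was chosen. H3K4me1 lists also had the lowest median fold enrichment of the 5 antibodies (3.01 averaged over animals), so weak signal there could be missed. General recovery of strong active chromatin stays open, as PolII_S5P at H3K27ac peaks of the regions was above matched peaks by 10.9 percentage points on average. The exact 95% intervals included the matched value in animals 5 (2.48 to 21.2% against 6.06%) and 7 (24.4 to 54.5% against 24.7%). In animal 9 the interval lay above it (16.1 to 45.5% against 13.3%). These H3K27ac peaks had median fold percentiles of 69.4, 76.0 and 30.2 in animals 5, 7 and 9, so in animal 9 they were not strong.

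The overlap of TDG with MBD3 could come from the libraries rather than from the proteins. Carry-over of MBD3 signal as the whole cause would place TDG at the strongest MBD3 peaks. In animals 5, 7 and 9, TDG lay at 93 of 57622, 90 of 62164 and 569 of 39326 MBD3 peaks. Of as many strongest MBD3 peaks, 2.15%, 2.22% and 9.67% had TDG. These shares are low but above those among all MBD3 peaks in every animal, so a partial carry-over stays open. A first bound on the median percentile (81.4, 73.3 and 73.2 in animals 5, 7 and 9) decided nothing. A control library particular to 1 animal would favour the MBD3 list of the same animal, but lists of equal length differed by 0.147 percentage points between same and other animals. The control of each library is not given, and a bias common to all control libraries would not show in this comparison, so it stays open. H3K27ac as the common cause would leave an odds ratio of 1 within strata of PolII_S5P, H3K4me1 and fold only if these captured it fully. The lowest of 3 was 2.54, or 4.37 with 10 classes of site width added (4.12 with 5 and 4.96 with 20), all intervals lying above 1. The strata thus did not remove the association, but variation of H3K27ac within them could still contribute. A shared processing of the MBD3 and TDG lists remains confounded with the antibodies.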
